A study of Arabidopsis thaliana with 16 samples.

How the data were processed

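RNA from Arabidopsis leaves was hybridized to Affymetrix ATH1 arrays, 16 arrays in 8 groups of 2, 5 days after inoculation of plants 4 weeks old or from uninfected plants. Per the labels, leaves for dissection and scraping were microwave-fixed, dehydrated, embedded in paraffin and sectioned, whole leaves were frozen in liquid nitrogen, and infected plants stood in a separate growth chamber. Targets were labelled in a single round or with a second round of amplification. The deposited values are log2 expression summaries, 1 per probe set, made by the authors; the submitters' processing notes name RMA and affy. Their versions, and whether all arrays were normalized together, are not given in the sources used here. The log2 scale was read from the values, and array medians differed between 3.27 and 4.06. The share of probe sets below log2 3 was between 30.7% and 47.2% per array. The number of arrays limits the precision.

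Of 22810 probe sets, 64 controls were left out and 22746 tested. The platform table listed 14016, of which 13513 stood for 1 gene and 503 for several; 8730 tested probe sets were unnamed here and were counted but never named. The 13513 covered 13355 genes, 147 of them with more than 1 probe set. Groups were taken from the labels, and no array was moved between groups.

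Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per group over all 16 arrays, no block, 8 residual and 1.29 prior degrees of freedom). Benjamini-Hochberg adjustment ran over all tested probe sets, and a call needed an adjusted p under 0.05. The 10 planned comparisons, their tests, their alternatives and 20 gene lists were fixed before the data were examined. The comparison of eds16 with wild type labelled uninfected was added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

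Of 420 entries in the 20 fixed lists, 48 had a named probe set. The lists for mildew penetration resistance and epidermis markers had 0, so neither gave a value, and lists with fewer than 3 named members were not tested as lists; that minimum was chosen after the list sizes were seen. A further 16 lists, with 450 of 550 entries named, were written once the data were at hand but before their values were examined. The ribosomal list among them had been planned by description, with its loci then written from memory. The entries TPI and DAD1 were dropped before their values were seen because the symbol belongs to another locus. The 24 lists with at least 3 named members were tested with camera (preset correlation 0.01, or an estimated correlation) against the rest of the 13355 named genes (1 probe set per gene), and with fry against no change, and adjusted over the 24.

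Named genes followed a rule set before the data were examined. It took 5 genes of prior interest, none of which had a named probe set, then the 8 largest rises and 8 largest falls in the first pair of comparisons and 4 of each in the others, among calls whose groups did not overlap, and up to 4 members of each described list by adjusted p. Errors of log2 changes are standard errors from the shared limma fit, with its moderated variance.

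The pipeline was tested on simulated data. The simulation shifted 200 probe sets per comparison, by log2 1 or log2 2. Between 15% and 46% of the smaller and between 43% and 82% of the larger shifts were recovered. False calls made up between 1.7% (site minus whole-leaf infection response) and 13.5% (amplification) of all calls. They made up 10.4% for infection at the dissected site and 2.2% for eds16 against infected wild type there. The shares for amplification and the dissected site exceeded the rate set by the adjusted p threshold, and the other shares given here did not. With 10 autophagy genes shifted by log2 1, that list was recovered in 11 of 11 comparisons and another list passed in 0. The simulated noise was independent between genes. This test therefore cannot show how often lists of correlated genes pass without a change. The measured groups also differed in spread, with median replicate SDs between 0.064 (uninfected amplified whole leaf) and 0.244 (scraped sections). How such unequal spread affects false calls was not tested. The comparisons that share arrays were also simulated 20 times with unchanged groups.

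The alternatives were a further quantile normalization, centring each array on its median, leaving out the lowest 0.25 of probe sets by mean, fitting only the arrays compared, a replicate block, an intensity trend with robust variance, leaving out probe sets that may cross-hybridize, leaving out the one-round arrays, a minimum change of log2 1, and leaving out each array in turn. Leaving out the scraped sections, leaving out the 16 later lists, dividing the arrays shared by the dissected comparisons, naming group means below log2 3, comparing the control gaps of eds16 and recomputing the correlations with each array left out were chosen after seeing the data.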

Results

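RNA was measured on 16 Affymetrix ATH1 arrays from Arabidopsis leaves, 5 days after inoculation with the powdery mildew fungus Golovinomyces orontii or from uninfected leaves. Plants were 4 weeks old at inoculation. The arrays form 8 groups of 2. Epidermal and mesophyll cells were cut by laser microdissection from fixed, paraffin-embedded sections of wild-type leaves labelled infected, wild-type leaves labelled uninfected, and infected leaves of eds16-1. The eds16-1 plant is a null mutant of isochorismate synthase 1, an enzyme of salicylic acid synthesis. Whole wild-type leaves, infected and uninfected, were measured after one-round labelling and after amplification; whether the same leaves served both is not given in the sources used here. A further group held scraped sections of infected wild-type leaf. Each array gave a log2 value for 22746 probe sets other than controls. Array medians lay between 3.27 and 3.38 in whole leaf, between 3.80 and 4.06 in dissected cells, and at 3.62 and 4.05 in the scraped sections. Replicate arrays correlated across probe sets with r between 0.931 (scraped sections) and 0.994 (uninfected amplified whole leaf), and 2 arrays per group limit the precision of every value. Where 2 groups are compared, a change to or from a group mean below log2 3 is read as a lower bound, and a difference between responses that rests on such a mean is no bound. Among the largest changes, genes with such a mean are named. Infected plants were kept in another growth chamber than uninfected ones, so infection and chamber were not separated in any comparison of infected with uninfected plants. No probe set named here stood for ICS1, PR1, MYB3R4, PUX2 or PEPR2, so the mutated gene gave no check of the labels. Counts of list members below cover only genes with a named probe set. These were 8 of 44 photosystem, 3 of 19 Calvin cycle, 3 of 14 chlorophyll, 3 of 17 folding, 3 of 34 salicylic acid and 4 of 17 heat-shock entries.

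The dissected wild-type arrays, taken as labelled, ran opposite to whole leaf. Across the 22746 probe sets, the change from labelled uninfected to labelled infected cells correlated with the change in amplified whole leaf at r = -0.382 (Spearman -0.219) and with that in one-round whole leaf at r = -0.355 (Spearman -0.353). One-round and amplified whole leaf correlated at r = 0.688 (Spearman 0.492). These 3 correlations are across probe sets, which are not independent replicates. Of 1436 probe sets called in amplified whole leaf, 22.9% had the same sign at the dissected site, against 92.8% in one-round whole leaf. In both whole-leaf comparisons 239 probe sets were called higher and 237 lower. Of the 239, 75 were called lower at the dissected site and 0 higher, and of the 237, 32 were called higher and 2 lower. The mean of the raised sets minus the mean of the lowered sets was -0.48 ± 0.04 (SD, n = 2) in dissected wild-type cells labelled infected, 0.96 ± 0.10 in those labelled uninfected and 0.32 ± 0.06 in eds16. It was 0.05 ± 0.10 in scraped sections, 2.84 ± 0.37 in infected and -1.56 ± 0.01 in uninfected amplified whole leaf, and 1.63 ± 0.18 and -2.24 ± 0.05 in one-round whole leaf. Directions drawn from the dissected wild-type arrays below are therefore given as labelled.

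**Figure D1:**
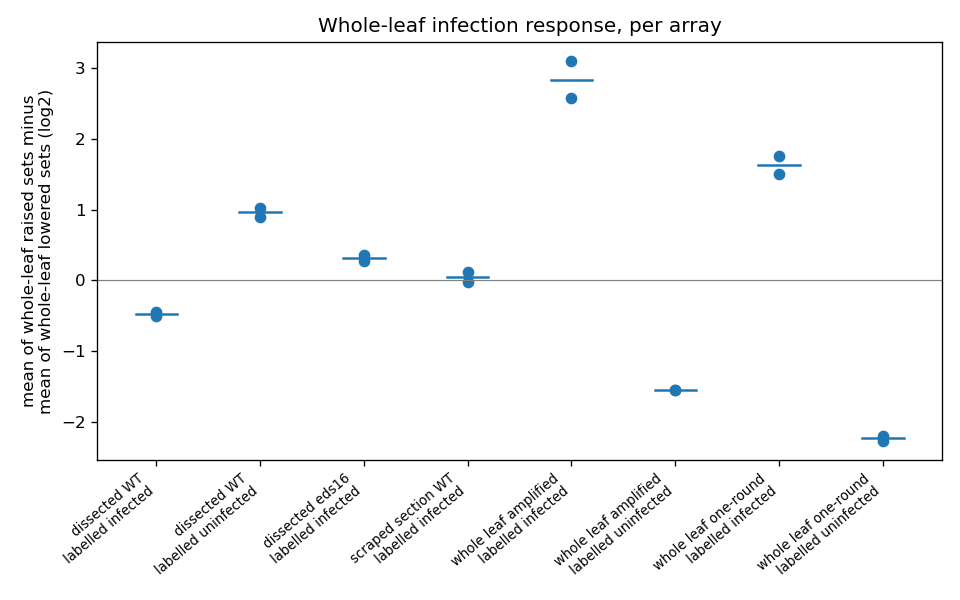
Each point is 1 array and each line the mean of the 2 in a group; the vertical axis is the mean log2 value of 239 probe sets raised in infected whole leaf minus that of 237 lowered there, by group. Dissected wild-type cells labelled uninfected lie at 0.96 and those labelled infected at -0.48, opposite to the order of the whole-leaf groups, which defined the sets.

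**Figure D2:**
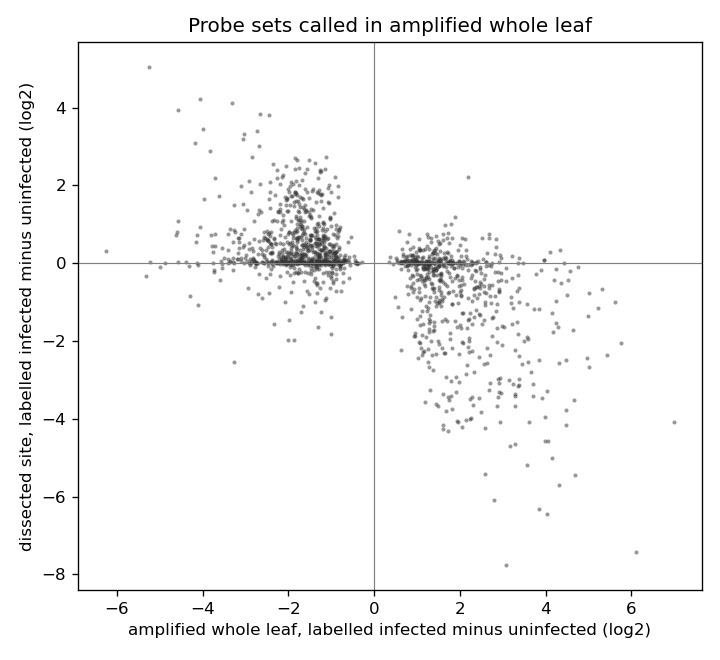
Each point is 1 of the 1436 probe sets called in amplified whole leaf, with its log2 change there on the horizontal axis and its log2 change between dissected cells labelled infected and uninfected on the vertical axis. 22.9% of the points have the same sign on both axes.

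The first comparison asked how cells at the infection site differ from cells of uninfected leaves. In dissected cells labelled infected, relative to those labelled uninfected, transcripts of photosynthesis and of the plastid genome were higher, and transcripts of protein folding, of the salicylic acid list and of autophagy were lower. With an estimated correlation folding and autophagy passed (adjusted p = 0.0431 and 0.0444) and the photosystem, chlorophyll, plastid-encoded and salicylic acid lists did not (adjusted p = 0.223, 0.237, 0.237 for each and 0.185). The largest rises were in AT4G18280 (log2 5.87 ± 0.33, SE, n = 2 per group, adjusted p = 3.54e-05), AT5G48490 (5.04 ± 1.11, adjusted p = 0.0235) and MSRB6, a methionine sulfoxide reductase (4.40 ± 0.99, adjusted p = 0.0257). AT2G05790, AT5G16030, AT5G01015, AT2G29290 and AT3G48420 rose by log2 4.23, 3.96, 3.94, 3.82 and 3.72. The largest falls were in AT3G18250 (-7.41 ± 1.18, adjusted p = 0.00509), AT1G65820 (-6.52 ± 0.41, adjusted p = 7.61e-05), AT1G76960 (-6.32 ± 0.94, adjusted p = 0.00368) and SAL2 (-5.44 ± 0.63, adjusted p = 0.00107). AT1G52200, YLS5, UBC30 (a ubiquitin-conjugating enzyme) and AT2G39400 changed by -5.37, -5.18, -5.17 and -5.08. SAL2 was among the largest rises in one-round whole leaf and AT3G18250 in amplified whole leaf. AT3G18250, SAL2 and AT1G52200 had group means below log2 3 in the cells labelled infected.

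Among the lists at the dissected site, 2 of 3 endoplasmic reticulum folding genes fell (adjusted p = 2.75e-05 for the list; adjusted p = 0.0431 with an estimated correlation), the calreticulin gene CRT1b by -4.22 ± 0.40 and the co-chaperone gene ATERDJ3B by -3.08 ± 0.40, while BZIP60 stood at -1.09. Of 3 salicylic acid genes, SAG101 (-2.35 ± 0.49), a partner of the immune regulator EDS1, and WRKY53 (-1.87 ± 0.49) fell and GRX480 stood at -2.46, not called (list adjusted p = 0.000955; adjusted p = 0.185 with an estimated correlation). Of 10 autophagy genes 7 fell (list adjusted p = 2.96e-08; adjusted p = 0.0444 with an estimated correlation), among them ATG8F (-2.62 ± 0.32), ATG8E (-2.02 ± 0.22) and ATG3 (-1.46 ± 0.20), an enzyme of ATG8 lipidation. BIK1, a receptor-associated kinase of pattern-triggered immunity, fell by 3.32 ± 0.53 (adjusted p = 0.0051), and AUR2, a mitotic kinase, rose by 2.03 ± 0.43 (adjusted p = 0.02). Cytosolic ribosomal protein genes, 21 of 114 of which fell, WRKY factors (1 of 6) and mitochondrially encoded genes (1 of 15) were lower as lists (adjusted p = 2.75e-16, 0.00857 and 0.000955; adjusted p = 0.185, 0.223 and 0.237 with an estimated correlation).

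Of 8 photosystem genes at the site 4 rose and 0 fell (list adjusted p = 0.00345; adjusted p = 0.223 with an estimated correlation), with PSBY at 1.61 ± 0.29, LHCB4.2 at 1.10 ± 0.18, LHCB4.1 at 1.09 ± 0.27 and ATPC1 at 0.71 ± 0.19. CHLM of chlorophyll synthesis rose by 2.90 ± 0.45, as 1 of 3 in its list (adjusted p = 0.0289; adjusted p = 0.237 with an estimated correlation). Of 3 Calvin cycle genes SBPASE rose (1.76 ± 0.30) and the list did not pass (adjusted p = 0.0759). Among plastid-encoded genes, 15 of 45 for photosynthesis and 11 of 20 for gene expression rose and 0 fell, among them psbE (2.40 ± 0.34) and rps16 (2.85 ± 0.40); both lists passed (adjusted p = 5.87e-10 and 1.64e-09; adjusted p = 0.237 for each with an estimated correlation). COR15A (2.36 ± 0.41) and COR47 (2.72 ± 0.51), cold-induced protectants, rose as 2 of 5 in a list that did not pass (adjusted p = 0.156). The AGAMOUS-like list passed upwards with 0 of 40 members called (adjusted p = 0.0244; adjusted p = 0.551 with an estimated correlation). Adjusted over the list alone, 3 of 3 folding genes and 3 of 3 salicylic acid genes fell, 4 of 8 photosystem, 2 of 3 Calvin cycle and 2 of 3 chlorophyll genes rose, and of 5 cold response genes 2 rose and 1 fell.

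In all, 723 probe sets were called higher and 1212 lower at the dissected site (limma, 16 arrays), and 11 of 24 lists passed, 2 of them with an estimated correlation. With arrays centred on their medians 20.9% of 1816 calls were higher, against 37.4%; with only the 4 arrays compared there were 327 calls, without the one-round arrays 1233, and without the scraped sections, a choice made after seeing the data, 4273, of which 61.6% were higher. Of the 8 largest rises, AT5G48490, MSRB6, AT2G05790, AT5G16030 and AT5G01015 missed the threshold with some array left out (adjusted p up to 0.148), and 0 of the 8 largest falls did. With only the arrays compared 5 of these rises and 5 of these falls missed it (falls up to adjusted p = 0.144).

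**Figure D3:**
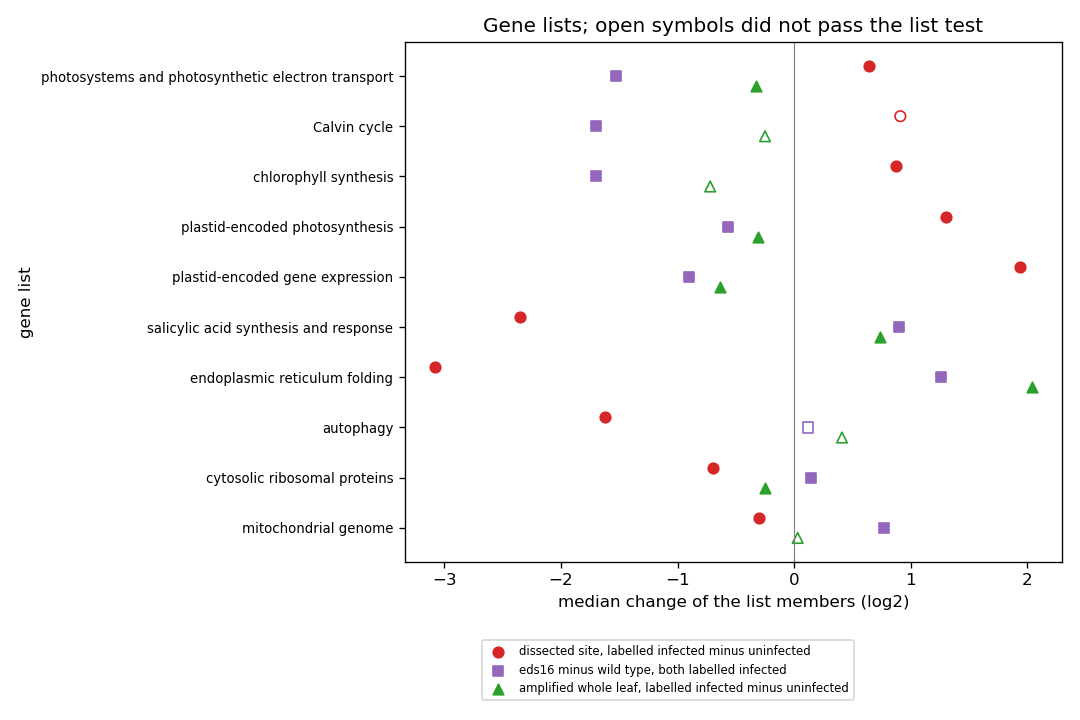
Median log2 change of the members (horizontal axis) of 10 gene lists (vertical axis) in 3 comparisons; filled symbols passed the list test with a preset correlation and open ones did not. The median of endoplasmic reticulum folding is -3.08 at the dissected site as labelled, 1.26 in eds16 against wild type and 2.04 in amplified whole leaf.

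The second comparison asked what loss of isochorismate synthase 1 changes in infected cells. In eds16 cells, relative to wild-type cells labelled infected, genes of photosynthesis were lower and genes of protein folding and of the mitochondrial genome were higher. With an estimated correlation the photosystem and Calvin cycle lists passed (adjusted p = 0.0126 and 0.0305) and folding and the mitochondrial genome did not (adjusted p = 0.0514 and 0.0602). Control transcripts of RNA length and 25S ribosomal RNA also differed between these groups, so RNA quality was not separated from the genotype. The wild-type label used here ran opposite to whole leaf, so infection was not surely equal in both groups. Against wild type labelled uninfected, folding genes were lower and plastid-encoded genes higher as lists with a preset correlation. The photosystem and Calvin cycle lists were lower there too, and none of these passed with an estimated correlation. AT3G18250 (5.98 ± 1.18, SE, n = 2 per group, adjusted p = 0.0205), AT1G52200 (5.15 ± 0.95, adjusted p = 0.0151) and AT2G39400 (5.09 ± 0.49, adjusted p = 0.000571) rose most, followed by AT4G38540, AT1G22890, AT1G72060, AT4G21870 and YLS5 (4.96, 4.75, 4.70, 4.24 and 4.08). AT1G12800 (-4.74 ± 0.53, adjusted p = 0.00128), AT2G21860 (-4.61 ± 0.40, adjusted p = 0.00036) and AT4G18280 (-4.56 ± 0.33, adjusted p = 0.000214) fell most. LrgB, AT1G74640, AT5G03350, LYC (lycopene cyclase, of carotenoid synthesis) and AT5G01015 followed at -4.55, -4.10, -4.05, -4.01 and -3.86. AT3G18250 and AT1G52200 had a group mean below log2 3 in wild type.

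In eds16 all 8 photosystem genes with a named probe set, of 44 listed, fell (list adjusted p = 3.22e-14). Among them were ATPC1 (-2.15 ± 0.19), PSBY (-1.97 ± 0.29), PSAE-1 (-1.65 ± 0.22) and LHCB4.2 (-1.41 ± 0.18). All 3 named Calvin cycle genes, of 19 listed, fell (list adjusted p = 7.21e-06): SBPASE (-2.34 ± 0.30), RCA, the activase of Rubisco (-1.70 ± 0.26), and PRK (-1.46 ± 0.29). PORB fell (-3.10 ± 0.46), as 1 of 3 chlorophyll synthesis genes (list adjusted p = 0.000154; adjusted p = 0.0602 with an estimated correlation). The cold and dehydration list was lower with 0 of 5 members called (adjusted p = 0.00445; adjusted p = 0.0639 with an estimated correlation). The plastid-encoded lists were lower with 2 of 45 and 0 of 20 members called (adjusted p = 4.87e-05 and 0.000154; adjusted p = 0.613 for both with an estimated correlation). Of 15 mitochondrially encoded genes 5 rose (list adjusted p = 8.84e-09; adjusted p = 0.0602 with an estimated correlation), matR by 2.06 ± 0.40 and ccb452 by 1.59 ± 0.28. CRT1b rose by 2.17 ± 0.40, as 1 of 3 folding genes (list adjusted p = 0.00101; adjusted p = 0.0514 with an estimated correlation). SAG101 rose by 2.40 ± 0.49, as 1 of 3 salicylic acid genes (list adjusted p = 0.0193; adjusted p = 0.305 with an estimated correlation), while WRKY53 and GRX480 stood at 0.78 and 0.90. Of 114 ribosomal protein genes 3 rose and 1 fell (list adjusted p = 0.0193, higher; adjusted p = 0.758 with an estimated correlation). When adjusted over the list alone, 8 of 8 photosystem, 3 of 3 Calvin cycle, 3 of 3 chlorophyll and 2 of 5 cold response genes fell, and 3 of 3 folding genes and 1 of 3 salicylic acid genes rose.

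In eds16, 456 probe sets were called higher and 554 lower. Leaving out either eds16 array turned this majority, with 60.4% of 1458 calls (replicate 1) and 58.9% of 1342 (replicate 2) higher, against 45.1%. In all 10 of 24 lists passed, 2 of them with an estimated correlation. Only the arrays compared gave 110 calls, and leaving out the one-round arrays 619; the ribosomal median turned from 0.14 to -0.01 without eds16 replicate 1. Of the 8 largest rises and 8 largest falls, 6 and 3 missed the threshold with some array left out (adjusted p up to 0.138 and 0.139). Under the other settings 7 and 7 did (adjusted p up to 0.231 and 0.258). Both dissected comparisons share the wild-type arrays labelled infected. They correlated at r = -0.611, with covariance -0.346, against a mean of -0.497 and -0.079 in 20 simulations of unchanged groups. Calls in opposite directions numbered 283 (higher at the site, lower in eds16) and 238 (the reverse). The simulations gave means of 0.3 and 0.4. Their groups were unchanged, so few calls could arise in either comparison, and these means are no reference for the overlap. An overlap with a real site effect and no eds16 effect was not simulated. With the shared arrays divided, 1 to each comparison and chosen after seeing the data, r was -0.428 and -0.443 and the covariance -0.274 and -0.28 for the 2 ways of dividing them. Calls in opposite directions then numbered 120 and 143, or 125 and 129, and calls in the same direction 38 or 41.

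In one-round whole leaf, infected leaves had higher SAL2 (4.01 ± 0.63, SE, n = 2 per group, adjusted p = 0.00729), AT1G26380 (3.96 ± 0.79), AT4G33980 (3.87 ± 0.37) and AT3G54150 (3.57 ± 0.66), and lower AT4G17470 (-5.50 ± 0.49, adjusted p = 0.000396), EXLA2, an expansin-like gene (-4.34 ± 0.61), AT5G01015 (-4.17 ± 0.84) and AT1G13650 (-4.15 ± 0.54). EXLA2 and AT1G13650 had group means below log2 3 in infected leaf. ATERDJ3B rose by 2.01 ± 0.40, as 1 of 3 folding genes (list adjusted p = 0.0217; adjusted p = 0.183 with an estimated correlation). Of 27 expansin and xyloglucan endotransglucosylase genes, which loosen cell walls, 3 fell and EXPA9 rose (1.06 ± 0.23); EXPB3 stood at -1.48 ± 0.19 and XTH16 at -2.91 ± 0.54 (list adjusted p = 0.000862, lower; adjusted p = 0.0509 with an estimated correlation). Of 14 SWEET sugar transporter genes 3 fell, SWEET4 by -1.30 ± 0.18, SWEET1 by -1.15 ± 0.11 and SWEET16 by -0.71 ± 0.11 (list adjusted p = 0.00125; adjusted p = 0.183 with an estimated correlation). AT5G61520, listed as the sugar transporter STP3, rose by 3.05 ± 0.41 in a list of 4 that did not pass (adjusted p = 0.865; its median and mean were above 0 and its test pointed lower). Of 11 tau glutathione transferases GSTU20 (-2.97 ± 0.53) and GSTU26 (-1.62 ± 0.28) fell, and of 114 ribosomal protein genes 4 fell (list adjusted p = 0.0356 and 7.75e-12; adjusted p = 0.428 and 0.337 with an estimated correlation). Plastid-encoded gene expression was lower and autophagy higher as lists, with 0 of 20 and 0 of 10 members called (adjusted p = 0.00272 and 0.0122; adjusted p = 0.536 and 0.337 with an estimated correlation).

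One-round whole leaf gave 567 probe sets higher and 438 lower, and 7 of 24 lists passed, 0 of them with an estimated correlation (3 at an unadjusted p under 0.05). With only its 4 arrays limma called 0 (4017 at an unadjusted p under 0.05), and without infected replicate 1 it called 525. Without uninfected replicate 1 the majority turned, with 42.1% of 705 calls higher against 56.4%. AT1G26380, AT3G54150 and AT5G01015 missed the threshold with some array left out (adjusted p up to 0.153). All 8 named genes missed it with only the arrays compared (adjusted p up to 0.209). Among fixed lists, adjusted over the list alone, 2 of 3 folding genes passed, in sugar transport 1 of 4 higher and 1 lower, and in the salicylic acid, photosystem, Calvin cycle, chlorophyll, cold and heat-shock lists 0.

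In amplified whole leaf, infected leaves had higher GH3.3, which conjugates auxin to amino acids (6.99 ± 0.73, SE, n = 2 per group, adjusted p = 0.000718), AT3G18250 (6.11 ± 1.18, adjusted p = 0.016), AT1G51890 (5.43 ± 0.42) and AT1G26420 (4.76 ± 0.20). They had lower AT4G17470 (-5.33 ± 0.49, adjusted p = 0.00033), AT5G48490 (-5.25 ± 1.11), ZW9 (-5.23 ± 0.63) and AT4G16563 (-5 ± 0.22). GH3.3, AT3G18250 and AT1G51890 had group means below log2 3 in uninfected leaf, and AT4G16563 in infected leaf. Of 3 folding genes ATERDJ3B (2.91 ± 0.40) and CRT1b (2.04 ± 0.40) rose (list adjusted p = 0.000398; adjusted p = 0.0726 with an estimated correlation). WRKY53 rose by 2.76 ± 0.49, as 1 of 3 salicylic acid genes (list adjusted p = 0.0477; adjusted p = 0.358 with an estimated correlation). XTH16 (-4.39 ± 0.54), EXLA2 (-4.58 ± 0.61), XTH33 (-3.74 ± 0.40) and EXLA1 (-3.70 ± 0.87) fell, as 4 of 27 wall-loosening genes (list adjusted p = 0.0148; adjusted p = 0.13 with an estimated correlation). CYP71B6 (2.21 ± 0.35), CYP71B23 (2.97 ± 0.69) and CYP71B24 (2.58 ± 0.36) rose among 26 cytochromes P450, and GSTU20 (-3.28 ± 0.53) and GSTU18 (-1.88 ± 0.47) fell among 11 tau glutathione transferases (list adjusted p = 0.0148 and 0.0154; adjusted p = 0.358 for both with an estimated correlation). SWEET4 fell (-1.07 ± 0.18) and AT5G61520 rose (2.33 ± 0.41) in a list of 4 that did not pass (adjusted p = 0.841). Photosystem, plastid photosynthesis and plastid gene expression lists were lower with 0 of 8, 0 of 45 and 0 of 20 members called (adjusted p = 0.0148, 0.00174 and 0.000909; adjusted p = 0.358, 0.493 and 0.418 with an estimated correlation). Of 114 ribosomal protein genes 5 fell and 1 rose (list adjusted p = 8.05e-05, lower; adjusted p = 0.358 with an estimated correlation). WRKY22 fell by 2.21 ± 0.55 and BCAT4, of glucosinolate synthesis, by 1.37 ± 0.33 (adjusted p = 0.0477 and 0.04). With p adjusted over the list alone, 3 of 3 folding, 1 of 3 salicylic acid and 1 of 4 heat-shock genes rose, 1 of 3 Calvin cycle and 1 of 3 chlorophyll genes fell, and 0 of 8 photosystem genes passed.

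Amplified whole leaf gave 622 probe sets higher and 814 lower, and 9 of 24 lists passed, 0 of them with an estimated correlation (2 at an unadjusted p under 0.05). Only its 4 arrays gave 368 calls, of which 59.5% were higher, and leaving out 1 array gave 872 (infected replicate 1, 58.9% higher), 779 (uninfected replicate 1) and 659 (uninfected replicate 2, 51.1% higher), against 43.3% higher with all arrays. AT3G18250 and AT5G48490 missed the threshold with some array left out (adjusted p up to 0.105 and 0.151). With only the arrays compared 1 of the 4 rises and 2 of the 4 falls missed it (adjusted p up to 0.0624 and 0.148). One-round and amplified leaf shared 239 probe sets called higher and 237 lower. The ubiquitin control's 3 prime minus 5 prime difference was 2.53 ± 0.10 (SD, n = 2) in infected and 3.01 ± 0.05 in uninfected amplified leaf. Those of actin and GAPDH lay within their spread. RNA quality was therefore not fully separated from infection in amplified leaf.

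The difference between the site response and the amplified whole-leaf response was tested directly. Folding genes differed as a list: CRT1b by -6.26 ± 0.57, ATERDJ3B by -5.98 ± 0.57 and BZIP60 by -1.91 ± 0.50, all 3 called lower at the site as labelled (list adjusted p = 1.4e-05; adjusted p = 0.0338 with an estimated correlation). The response of AT5G48490 was higher at the site by 10.29 ± 1.57 (SE, n = 2 per group), that of AT5G01015 by 8.51 ± 1.19, of AT1G09750 by 8.46 ± 1.77 and of AT2G05790 by 8.30 ± 1.37. It was lower for AT3G18250 (-13.52 ± 1.67), GH3.3 (-11.07 ± 1.04), AT1G76960 (-10.18 ± 1.33) and SAL2 (-10.13 ± 0.89). The sign, size and rank of all these differences depend on the dissected wild-type labels. For example, AT3G18250 changed by -7.41 at the site as labelled and by 6.11 in amplified leaf, and exchanged labels would turn the first value. AT3G18250, GH3.3, SAL2 and AT1G09750 rest on at least 1 group mean below log2 3. WRKY53 (-4.63 ± 0.70) and SAG101 (-3.09 ± 0.69) were lower, as 2 of 3 salicylic acid genes, and PSBY (2.48 ± 0.41), SBPASE (2.70 ± 0.43) and CHLM (4.60 ± 0.63) higher, as 4 of 8, 1 of 3 and 1 of 3 in the photosystem, Calvin cycle and chlorophyll lists. Those 4 lists had adjusted p = 0.000881, 0.000881, 0.0454 and 0.0259, and adjusted p = 0.165, 0.165, 0.223 and 0.223 with an estimated correlation. Autophagy genes were lower in 7 of 10 (list adjusted p = 3.91e-07; adjusted p = 0.0653 with an estimated correlation), and plastid-encoded genes higher in 14 of 45 and 12 of 20 (adjusted p = 2.41e-09 for both; adjusted p = 0.256 and 0.223 with an estimated correlation). The wall-loosening list (4 of 27) and the tau glutathione transferases (2 of 11) were higher, and WRKY factors (2 of 6), mitochondrial genes (1 of 15) and ribosomal protein genes (7 of 114 lower, 1 higher) lower. Their adjusted p was 0.0444, 0.0305, 0.0149, 0.00608 and 0.000795, and adjusted p = 0.165, 0.256, 0.223, 0.256 and 0.362 with an estimated correlation. Over the list alone, that is with p adjusted over the list alone, 3 of 3 folding and 3 of 3 salicylic acid genes were lower and 4 of 8 photosystem, 2 of 3 Calvin cycle and 1 of 3 chlorophyll genes higher.

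The test of this difference called 1200 probe sets higher and 1483 lower at the site, and 13 of 24 lists passed, 1 of them with an estimated correlation. All 8 genes with the largest differences kept their call with each array left out, and 1 missed the threshold with only the arrays compared (adjusted p = 0.0715). Leaving out uninfected amplified replicate 1 gave 1731 calls, 50.7% of them higher, and replicate 2 gave 1698. Without the scraped sections, chosen after seeing the data, 2224 were higher and 1794 lower. Site and amplified leaf calls overlapped in opposite directions in 177 and 126 probe sets, against 33.1 and 25.9 for independent lists, and in the same direction in 3 (higher) and 11 (lower), against 19.8 and 43.4.

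The test of a difference in infection response between labelling methods had little power, recovering 18% of simulated differences of log2 1 and 44% of log2 2. The amplified response minus the one-round response was positive for LUP5 (3.35 ± 0.39, SE, n = 2 per group, adjusted p = 0.00827), TCP15 (2.94 ± 0.31), AT1G06000 (2.71 ± 0.48) and AT1G04800 (2.12 ± 0.30). It was negative for AT4G16563 (-3.77 ± 0.31, adjusted p = 0.00166), AT5G42200 (-2.66 ± 0.25), AT5G13400 (-2.23 ± 0.36) and AT3G62000 (-2.18 ± 0.12). LUP5, TCP15, AT4G16563, AT5G42200 and AT3G62000 rest on at least 1 group mean below log2 3. For TCP15 the difference lies in one-round leaf (5.94 uninfected, 2.99 infected), with 2.15 and 2.14 after amplification. For AT1G04800 it lies there too (6.23 and 4.11, against 3.86 and 3.87). SWEET1, which fell in one-round leaf, differed by 1.15 ± 0.16 (adjusted p = 0.014). In all 57 probe sets were called higher and 71 lower (limma), 1459 passed at an unadjusted p under 0.05, and 0 of 24 lists passed (7 at an unadjusted p under 0.05; fry 0, with 2 unadjusted; an estimated correlation 0, with 1; up to 3 passed with 1 array left out). Median centring gave 37 calls, leaving out dim probe sets 15, only these arrays 15, and an intensity trend with robust variance 82. Leaving out infected amplified replicate 2 gave 412 and infected one-round replicate 2 gave 243, and AT1G06000, AT1G04800 and AT5G13400 missed the threshold with some array left out (adjusted p up to 0.152). Under other settings 4 of the 4 rises and 3 of the 4 falls missed it (adjusted p up to 0.389 and 0.236).

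Amplified was also set against one-round whole leaf, averaged over infected and uninfected leaves. Whether the same leaves served both is not given, so amplification was not separated from a difference between leaves. AT2G07708 (3.43 ± 0.32, SE, 4 arrays against 4, adjusted p = 0.000132), the mitochondrial gene cox1 (3.13 ± 0.19), AT5G47400 (2.98 ± 0.32) and AT4G35985 (2.66 ± 0.28) were higher after amplification. AT2G45670 (-5.12 ± 0.09, adjusted p = 1.27e-08), the plastid gene psaA (-5.03 ± 0.87), AT5G13030 (-4.82 ± 0.51) and AT4G16490 (-4.65 ± 0.22) were lower. AT2G45670 and AT4G16490 had means below log2 3 in both amplified groups. WRKY53 (1.65 ± 0.35) and GRX480 (1.83 ± 0.46) were higher, as 2 of 3 salicylic acid genes; RCA (-1.02 ± 0.18) and SBPASE (-0.96 ± 0.22) lower, as 2 of 3 Calvin cycle genes; COR15A (-2.77 ± 0.29) and LTI30 (-1.54 ± 0.29) lower, as 2 of 5 cold response genes; and SWEET4 (-1.76 ± 0.12) lower, as 1 of 4 sugar transport genes. These 4 lists passed (adjusted p = 0.0179, 0.0239, 0.000931 and 0.0179; adjusted p = 0.309, 0.287, 0.103 and 0.208 with an estimated correlation), and adjusted over the list alone 3 of 3, 2 of 3, 5 of 5 and 1 of 4 members passed. Among other lists, 6 of 15 mitochondrial and 7 of 47 UDP-glycosyltransferase genes rose (1 of the 47 fell), and 3 of 14 SWEET and 5 of 27 wall-loosening genes fell (adjusted p = 0.00743, 0.0179, 0.0179 and 0.0405; adjusted p = 0.336, 0.336, 0.288 and 0.208 with an estimated correlation). Plastid gene expression (1 of 20 rose, 4 fell) and ribosomal protein genes (9 of 114 rose, 12 fell) were lower (adjusted p = 0.0179 and 0.0416; adjusted p = 0.734 and 0.781 with an estimated correlation). The SWEET median was 0.01 and its mean -0.36. After a further quantile normalization the ribosomal median was 0.01, against -0.07, and that list did not pass (camera adjusted p = 0.924). PDF1.2, a defensin of the jasmonate response, fell by 3.14 ± 0.38, SIM of the endocycle by 1.67 ± 0.33 and FMA, a guard cell regulator, by 1.02 ± 0.24. In all 1302 probe sets were called higher and 2072 lower, 10 of 24 lists passed (5 without infected one-round replicate 2), 0 of them with an estimated correlation (4 at an unadjusted p under 0.05), and 2091 calls were of at least log2 1. The 3 prime minus 5 prime difference of the actin control was 2.61 ± 0.56 (SD, n = 2) in one-round infected leaf and 6.99 ± 0.45 after amplification, and that of GAPDH 1.19 ± 0.37 and 5.17 ± 0.42. The 25S ribosomal RNA control rose from 4.35 ± 1.10 to 12.68 ± 0.08.

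Scraped fixed sections, set against amplified infected whole leaf, had far more heat-shock and mitochondrial RNA. Control transcripts of RNA length differed as well. The GAPDH 3 prime minus middle difference was 4.15 ± 0.14 (SD, n = 2) in scraped sections and 1.26 ± 0.28 in amplified infected leaf. RNA quality was therefore not separated from preparation in this comparison. All 4 heat-shock genes with a named probe set, of 17 listed, rose (median 7.55, list adjusted p = 3.36e-05, adjusted p = 0.115 with an estimated correlation). Among them were AT1G53540 (9.16 ± 0.37, SE, n = 2 per group, adjusted p = 5.49e-07) and AT2G29500 (8.47 ± 0.32), both listed as small heat-shock proteins. Of 15 mitochondrially encoded genes 13 rose (median 4.72, list adjusted p = 2.27e-10; adjusted p = 0.115 with an estimated correlation), nad6 by 8.34 ± 0.24 and nad5 by 8 ± 0.24. The mean of nad6 was 2.56 in whole leaf, and that of AT4G12490 was below log2 3 in scraped sections. AT1G54050 (11.18 ± 0.23) and AT5G48570 (9.85 ± 0.34) rose most of all named genes, and AT5G18470 (-6.61 ± 0.41), AT3G23550 (-6.55 ± 0.93), AT4G12490 (-6.30 ± 1.56) and AT2G39210 (-6.15 ± 0.63) fell most. SWEET11, the only vascular marker with a named probe set, fell by 3.15 ± 0.58, PDF1.2 by 3.4 ± 0.54, UGT74B1 by 3.35 ± 0.42 and BIK1 by 3.6 ± 0.53, and AUR2 rose by 1.67 ± 0.43.

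Photosystem, Calvin cycle and chlorophyll genes were lower in scraped sections (3 of 8, 3 of 3 and 2 of 3 fell), with ATPC1 at -1.73 ± 0.19, PRK at -1.81 ± 0.29 and PORB at -3.02 ± 0.46. ATERDJ3B fell by 2.81 ± 0.40, as 1 of 3 folding genes. These 4 lists had adjusted p = 0.000553, 0.0142, 0.025 and 0.0459, and adjusted p = 0.194, 0.205, 0.222 and 0.205 with an estimated correlation. After a further quantile normalization none of these 4 passed, and 3 of 24 lists did, against 9. Autophagy genes (2 of 10 fell, ATG3 by -3.48 ± 0.20), ribosomal protein genes (23 of 114 fell, 8 rose) and AGAMOUS-like genes (9 of 40 rose, 1 fell) also passed (adjusted p = 0.0127, 0.00423 and 0.0142; adjusted p = 0.222, 0.668 and 0.671 with an estimated correlation). After that normalization the ribosomal median was 0.40, against -0.20, with its test turned (adjusted p = 0.0759), and the autophagy median 0.07, against -0.71 (adjusted p = 0.635). With p adjusted over the list alone in scraped sections, 4 of 4 heat-shock genes rose and 6 of 8 photosystem, 3 of 3 Calvin cycle, 2 of 3 chlorophyll and 2 of 3 folding genes fell. In all 3114 probe sets were called higher and 4128 lower, with a median log2 change of 0.089 over all of them, and 9 of 24 lists passed, 0 of them with an estimated correlation (5 at an unadjusted p under 0.05); with arrays centred on their medians 19.1% of 9663 calls were higher, against 43%. Only the 4 arrays compared gave 1394 calls, and leaving out infected amplified replicate 2 gave 4002. With an intensity trend and robust variance 4700 were higher and 4244 lower, and without scraped replicate 1, 55.8% of 9306 were higher. AT4G12490 missed the threshold with some array left out (adjusted p up to 0.0819), and 2 of the 4 falls with only the arrays compared (adjusted p up to 0.0957).

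**Figure D4:**
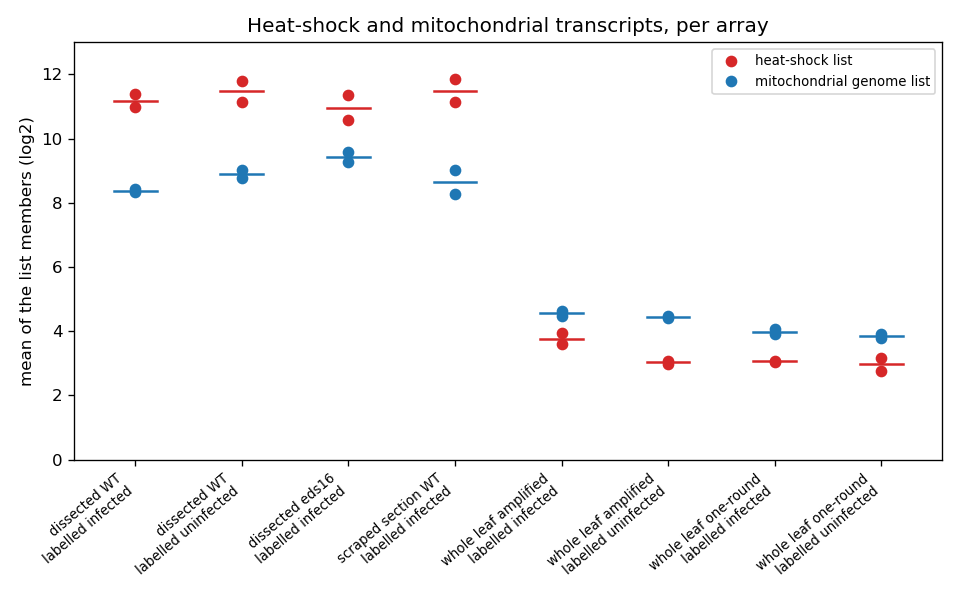
Mean log2 value of the 4 heat-shock genes and of the 15 mitochondrially encoded genes on each array (points), with the mean of each group of 2 (lines). The heat-shock mean is 10.57 or higher on every array from fixed sections, whatever its label, and 3.95 or lower on every whole-leaf array.

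Dissected cells labelled infected, set against scraped sections of infected leaf, were higher in plastid transcripts (adjusted p = 0.367 with an estimated correlation) and lower in BCAT4, an enzyme of methionine-derived glucosinolate synthesis (-5.86 ± 0.33, SE, n = 2 per group, adjusted p = 6.24e-05). AT5G04610 (3.03 ± 0.15), HEME1 of tetrapyrrole synthesis (2.97 ± 0.57), AT5G02940 (2.77 ± 0.32) and AT2G34620 (2.69 ± 0.28) rose most. AT1G67865 (-5.48 ± 0.56), AT1G65820 (-5.40 ± 0.41) and AT2G05540 (-5.25 ± 0.70) fell most besides BCAT4. Of the plastid-encoded genes 10 of 45 for photosynthesis and 4 of 20 for gene expression rose, ndhK by 2.65 ± 0.27 and rps16 by 2.13 ± 0.40 (list adjusted p = 4.87e-12 and 3.93e-07; adjusted p = 0.367 for both with an estimated correlation). The scraped arrays differed here, and without scraped replicate 2 neither list passed (adjusted p = 0.071 for plastid-encoded photosynthesis and 0.445 for plastid-encoded gene expression). AT5G04610 had a mean below log2 3 in scraped sections, and BCAT4 and AT2G05540 in dissected cells. Of 10 autophagy genes 4 fell, ATG8F by -2.61 ± 0.32, and CRT1b fell by 2.3 ± 0.40 as 1 of 3 folding genes (list adjusted p = 4.11e-06 and 0.00318; adjusted p = 0.107 for both with an estimated correlation). Ribosomal protein genes (6 of 114 fell) and salicylic acid genes (0 of 3 called) were lower, and chlorophyll (0 of 3) and AGAMOUS-like genes (0 of 40) higher, as lists (adjusted p = 3.93e-07, 0.0219, 0.0272 and 0.013; adjusted p = 0.367, 0.367, 0.367 and 0.662 with an estimated correlation). Among fixed lists, with p adjusted over the list alone, 2 of 3 folding and 2 of 3 salicylic acid genes fell, and 2 of 3 chlorophyll, 2 of 3 Calvin cycle and 2 of 8 photosystem genes rose.

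Dissected against scraped tissue gave 305 probe sets higher and 549 lower; with arrays centred on their medians 147 of 808 calls were higher. Of 24 lists 8 passed, 0 of them with an estimated correlation (2 at an unadjusted p under 0.05), and without scraped replicate 1 or 2 the count was 4 or 5. Without scraped replicate 2 there were 4666 calls, 64.5% of them higher against 35.7%, and without the one-round arrays 460, and with only the 4 arrays compared limma called 0 (1984 at an unadjusted p under 0.05). HEME1 missed the threshold without dissected replicate 2 (adjusted p = 0.0922). All 8 named genes missed it with only the arrays compared (adjusted p up to 0.441). The wild-type arrays used are those whose label ran opposite to whole leaf. Control transcripts of RNA length differed too. The 3 prime minus middle difference of ubiquitin was 3.34 ± 0.06 (SD, n = 2) in the dissected cells and 4.16 ± 0.12 in scraped sections. That of GAPDH went the other way, at 4.61 ± 0.15 and 4.15 ± 0.14. RNA quality was therefore not separated from dissection here.

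In dissected cells labelled uninfected, set against amplified uninfected whole leaf, all 4 named heat-shock genes again were higher (median 8.79, list adjusted p = 3.94e-05, adjusted p = 0.0868 with an estimated correlation). AT1G53540 was higher by 9.89 ± 0.37 (SE, n = 2 per group, adjusted p = 3.6e-07). AT5G48570 (9.89 ± 0.34), nad5 (9.47 ± 0.24) and Hop3 (9.06 ± 0.34) were the other largest rises. Mitochondrially encoded genes were higher in 13 of 15 (median 5.01, list adjusted p = 3.08e-10; adjusted p = 0.0836 with an estimated correlation). AT1G66100 (-8.07 ± 0.56), BCAT4 (-7.96 ± 0.33), AT1G09750 (-7.65 ± 1.25) and the glucosinolate transporter gene GTR1 (-7.51 ± 1.11) fell most. AT1G53540, nad5 and Hop3 had means below log2 3 in whole leaf, and BCAT4, AT1G09750 and GTR1 in dissected cells. AT2G31790, listed under aliphatic glucosinolate synthesis, fell by 4.2 ± 0.44, and UGT74B1, listed under indole glucosinolate synthesis, by 2.97 ± 0.42. SWEET11, the vascular marker, fell by 2.85 ± 0.58, PDF1.2 fell by 3.47 ± 0.54, and PRL of DNA replication rose by 1.43 ± 0.40. WRKY53 and GRX480 rose by 2.15 ± 0.49 and 2.84 ± 0.66, and CRT1b by 2.82 ± 0.40, in lists that did not pass (adjusted p = 0.23 and 0.0876).

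Control transcripts of RNA length and 25S ribosomal RNA also differed in this comparison, so RNA quality was not separated from dissection. The dissected arrays used are among those whose label ran opposite to whole leaf, so a difference in infection is not excluded either. Photosystem (7 of 8), Calvin cycle (3 of 3), chlorophyll (3 of 3) and cold response genes (3 of 5, with STZ higher at 1.76 ± 0.45) were lower in the dissected cells labelled uninfected, with ATPC1 at -2.59 ± 0.19, SBPASE at -2.76 ± 0.30, PORB at -3.73 ± 0.46 and LTI30 at -4.56 ± 0.41. The 4 lists had adjusted p = 2.84e-06, 0.00338, 0.00338 and 0.0445, and adjusted p = 0.0836, 0.113, 0.153 and 0.193 with an estimated correlation. Plastid photosynthesis (16 of 45 fell, 2 rose), ribosomal protein (21 of 114 fell, 10 rose) and AGAMOUS-like genes (14 of 40 rose, 1 fell) passed as well (adjusted p = 0.00225, 0.00923 and 0.0193; adjusted p = 0.546 for each with an estimated correlation). After a further quantile normalization the ribosomal median turned from -0.23 to 0.41 and that list passed as higher (adjusted p = 0.0322), so its direction is not settled. The plastid median turned from -0.61 to 0.06 (adjusted p = 0.846). With arrays centred on their medians the AGAMOUS-like median turned from 0.42 to -0.09 and the list did not pass (adjusted p = 0.0512). With p adjusted over the list alone, 4 of 4 heat-shock and 3 of 3 folding genes rose and 7 of 8 photosystem, 3 of 3 Calvin cycle, 3 of 3 chlorophyll and 3 of 5 cold response genes fell. In all 3704 probe sets were called higher and 4318 lower, with a median log2 change of 0.1 over all of them, and 9 of 24 lists passed, 0 of them with an estimated correlation (5 at an unadjusted p under 0.05); with arrays centred on their medians 19.8% of 11503 calls were higher, against 46.2%. Leaving out uninfected amplified replicate 2 gave 4974 calls. The majority turned with an intensity trend and robust variance (5374 higher, 4385 lower), with only the arrays compared (51.1% of 8166 higher) and without the scraped sections (4747 higher, 4557 lower), a choice made after seeing the data.

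Control transcripts described the RNA itself. In dissected cells the 3 prime minus 5 prime difference of actin was 7.18 ± 0.00 in wild type labelled infected, 7.73 ± 0.22 (SD, n = 2 per group) in wild type labelled uninfected and 7.60 ± 0.17 in eds16, and that of ubiquitin was 3.15 ± 0.11, 3.87 ± 0.27 and 3.78 ± 0.08. The 3 prime minus middle difference of GAPDH was 4.61 ± 0.15, 3.19 ± 0.02 and 3.96 ± 0.11. Of the 6 such gaps, labelled infected cells were lower than labelled uninfected ones by over 2 SE in 3 and higher in 1, beside the gene groups compared between those labels. In eds16, 4 of the 6 gaps were higher than in labelled infected cells by over 2 SE and 1 lower, and 2 were higher than in labelled uninfected cells and 0 lower. The 3 prime minus middle difference of actin was 3.12 ± 0.06 in eds16 and 2.60 ± 0.17 in labelled infected cells. In scraped sections the gaps were 8.08 ± 0.64 (GAPDH 3 prime minus 5 prime), 4.15 ± 0.14 (GAPDH 3 prime minus middle) and 2.82 ± 0.17 (actin 3 prime minus middle), against 5.17 ± 0.42, 1.26 ± 0.28 and 1.49 ± 0.23 in amplified infected leaf. In those labelled cells the 25S ribosomal RNA control stood at 13.94 ± 0.13 (infected) and 14.43 ± 0.20 (uninfected), and in eds16 at 14.62 ± 0.30. In uninfected amplified leaf it was 12.58 ± 0.06, and the 3 prime minus middle difference was 1.17 ± 0.28 for GAPDH and 1.36 ± 0.07 for actin, against 2.57 ± 0.02 for actin in labelled uninfected cells.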

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

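All tests of explanations in this part were chosen after the result they address had been seen, and the tests of sectioning and of a local response were reworded after a first run had been seen, which turned the sectioning outcome from undecided to favourable and left the other undecided. The infection responses of dissected cells and of amplified whole leaf were tested for a difference, and so were those of one-round and amplified leaf; the differences between responses given here come from those tests. The site response differed from that of amplified leaf in 2683 probe sets, and the amplified from the one-round response in 128.

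The dissected-site response, as labelled, ran opposite to the whole-leaf response. On the whole-leaf score, the cells labelled uninfected stood 0.91 above scraped sections of infected leaf, and the cells labelled infected stood 0.53 below them. Exchanged labels of the dissected wild-type arrays would give this order. The score also moved with preparation, at 0.05 in scraped sections of infected leaf and 2.84 in infected amplified leaf. A gap between dissected and scraped tissue therefore need not reflect infection. Such an exchange remains a hypothesis. None of the genes of prior interest, the mutated gene among them, had a named probe set. Named genes called in both whole-leaf comparisons are part of the score itself, so they give no separate check of the labels. Unnamed probe sets were also looked at, with their genes recalled from memory. Their identity could not be checked here, so that look is not used as evidence for or against an exchange. RNA length (3 control gaps lower and 1 higher, of 6) and a local response opposite to that of the leaf (eds16 at -0.64 from the labelled uninfected and 0.80 from the labelled infected arrays) cannot be told apart from it, because the gaps had no single side and eds16 lay between both labels. No group of cells away from infection sites in infected leaves is among those compared, so a local response stays open as biology.

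The eds16 comparison mirrored the dissected-site comparison. Chance values of the shared labelled infected arrays gave covariances between -0.082 and -0.075 in simulation, against -0.346 observed, so they do not account for all of it; with 1 shared array given to each comparison the covariance was -0.274 or -0.28. The eds16 change correlated with the amplified whole-leaf change at r = 0.347 (0.293 to 0.351 with each array left out), with no arrays in common. Exchanged labels of the dissected wild-type arrays would give this sign. However, the eds16 change uses the same labelled infected arrays as the site comparison, which correlated with amplified leaf at r = -0.382. The value is therefore no independent support for an exchange. An effect of the mutation itself, or of RNA quality, stays open and was not separated from an exchange.

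Heat-shock and mitochondrial transcripts stood high in fixed sections. The second round of amplification changed their medians by 0.32 and 0.39 in whole leaf, far less than the sections did. Infection alone would leave uninfected sections low, yet the lowest dissected wild-type array of either label stood 7.04 above the highest amplified whole-leaf array in the heat-shock mean. Scraped sections, which saw no laser, showed 7.55 and 4.72, but that test is not counted for fixation, embedding and sectioning, since its wording was fitted to known values. These steps stay open, because they, the handling of leaves before them and the extraction of sections always came together here.

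The medians of lists that differed between site and amplified leaf were lower at the site for salicylic acid (-3.09), endoplasmic reticulum folding (-5.98), cytosolic ribosomal proteins (-0.22), the mitochondrial genome (-0.58), WRKY factors (-1.16) and autophagy (-1.93). They were higher for photosystems (1.16), the Calvin cycle (1.15), chlorophyll synthesis (1.59), plastid-encoded photosynthesis (1.62), plastid-encoded gene expression (2.71), expansins and xyloglucan endotransglucosylases (0.37) and tau glutathione transferases (0.48). With an estimated correlation only folding passed (adjusted p = 0.0338). These differences, and those of single genes in the next paragraph, take the labels of the dissected wild-type arrays as given. With exchanged labels the site part of each would change sign.

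Responses higher at the site were those of AT4G18280 (5.2), AT5G48490 (10.29), MSRB6 (6.66), AT2G05790 (8.3), AT5G16030 (6.88), AT5G01015 (8.51), AT2G29290 (6.28), AT3G48420 (5.01), AT4G17470 (5.01), ZW9 (5.25), AT4G16563 (4.92), AT1G09750 (8.46), PSBY (2.48), LHCB4.2 (1.35), ATPC1 (1.05), LHCB4.1 (1.43), SBPASE (2.7) and CHLM (4.6). Responses lower at the site were those of AT3G18250 (-13.52), AT1G65820 (-7.92), AT1G76960 (-10.18), SAL2 (-10.13), AT1G52200 (-7.72), YLS5 (-8.76), UBC30 (-5.7), AT2G39400 (-6.49), GH3.3 (-11.07), AT1G51890 (-7.79), AT1G26420 (-4.87), WRKY53 (-4.63), SAG101 (-3.09), CRT1b (-6.26), ATERDJ3B (-5.98) and BZIP60 (-1.91). AT3G18250, SAL2, AT1G52200, GH3.3, AT1G51890, AT4G16563 and AT1G09750 rest on at least 1 group mean below log2 3, so their differences are not bounds in either direction.

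Between amplified and one-round leaf the response differed for LUP5 (3.35), TCP15 (2.94), AT1G06000 (2.71), AT1G04800 (2.12), AT4G16563 (-3.77), AT5G42200 (-2.66), AT5G13400 (-2.23) and AT3G62000 (-2.18). LUP5, TCP15, AT4G16563, AT5G42200 and AT3G62000 rest on such low means.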

How the results depend on the processing

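Leaving out the scraped sections, leaving out the later lists, dividing the shared arrays, the correlations with an array left out and everything on the added comparison of eds16 with wild type labelled uninfected were chosen after the result was seen; the other alternatives were planned. Of the values for named genes under alternatives other than leaving out an array, 4000 kept direction and call, 631 kept direction and missed the threshold, and 1 reversed; for lists, by the direction of the list test, the numbers were 738, 80 and 3. With an array left out they were 2071, 633 and 0 for genes and 387, 84 and 1 for lists, where the lone array of a group is assumed to vary like the other groups. Of counts of calls, 87 stayed within 1.5 times and 18 did not, and with an array left out 45 and 11. The level of the mutated gene gave no value, so its alternatives could not be run; median centring cannot move the control gaps, which lie within an array. Between 30.7% and 47.2% of probe sets lay below log2 3, where changes are hard to see. Except where fewer arrays, genes or lists entered by construction, the cause was not tested.

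Replicate numbers did not pair the arrays (28 pairs of groups, r between -0.27 and 0.23). With a replicate block the calls were 1777 at the site, 916 for eds16, 896 for one-round leaf, 1303 for amplified leaf, 2521 for site minus leaf, 93 for amplified minus one-round, 3264 for amplification, 6895 for scraped sections, 744 for dissection against scrape, 7778 for dissection against uninfected leaf and 1094 for the added comparison.

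With only the arrays compared, calls were 327 at the site, 110 for eds16, 0 for one-round leaf (limma, 4017 at an unadjusted p under 0.05), 368 for amplified leaf, 15 for amplified minus one-round (4 lists), 1394 for scraped sections, 0 for dissection against scrape (1984 unadjusted) and 0 for the added comparison (4506 unadjusted), and the overlap of infection and eds16 calls was 21. Without the one-round arrays they were 1233 at the site, 619 for eds16, 460 for dissection against scrape and 687 for the added comparison, with an overlap of 295. Without the scraped sections they were 4273 at the site and 2692 for the added comparison, with an overlap of 862 and 3 lists for amplified minus one-round. A minimum change of log2 1 left 2091 calls for amplification. Amplified minus one-round gave 37 calls with median centring, 15 without dim probe sets and 82 with an intensity trend and robust variance.

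Lists passing with an estimated correlation were 2 at the site, 2 for eds16, 0 for one-round leaf, 0 for amplified leaf, 1 for site minus leaf, 0 for amplification, 0 for scraped sections, 0 for dissection against scrape, 0 for dissection against uninfected leaf and 0 for the added comparison (camera; at an unadjusted p under 0.05, 4, 6, 3, 2, 5, 4, 5, 2, 5 and 4). With fry they were 6 for eds16, 3 for one-round leaf, 2 for amplified leaf, 4 for dissection against scrape and 18 for dissection against uninfected leaf. Without the lists written later they were 4 at the site, 6 for eds16, 1 for one-round leaf, 3 for amplified leaf, 5 for site minus leaf, 4 for amplification, 5 for scraped sections, 3 for dissection against scrape and 3 for the added comparison. Quantile normalization left 2 for amplified minus one-round and 3 for scraped sections, median centring 4 for scraped sections, and leaving out dim probe sets 4 for scraped sections and 4 for amplification.

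Quantile normalization moved the correlation of infection responses across genes: infection at the dissected site and infection in whole leaf, amplified, to r = -0.411. It turned the ribosomal median to 0.4 in scraped sections and 0.41 in dissected against uninfected leaf, and in the latter plastid-encoded photosynthesis to 0.06 and ATG8C to 0.14. The median of the list autophagy, fixed section scrape against whole leaf, also turned, to 0.07, while its test kept its direction (adjusted p = 0.635). The ribosomal list in dissected against uninfected leaf passed as higher (adjusted p = 0.0322). Median centring turned the AGAMOUS-like median there to -0.09 (adjusted p = 0.0512). For amplification the SWEET median, 0.01, turned to -0.02 with quantile normalization, -0.01 with median centring and -0.19 without dim probe sets. The ribosomal median for amplification, -0.07, turned to 0.01 with quantile normalization, and that list did not pass (camera adjusted p = 0.924). It was also 0.01 without infected one-round replicate 1.

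The majority direction of calls turned in some settings. Higher calls made up 53.6% for eds16, 47.9% for one-round leaf and 50.6% for scraped sections after quantile normalization. With only the arrays compared they made up 59.5% for amplified leaf, 73.3% for amplified minus one-round and 51.1% for dissection against uninfected leaf. With an intensity trend and robust variance they made up 52.5% for scraped sections and 55.1% for dissection against uninfected leaf. Without the scraped sections they made up 61.6% at the site, 55.4% for site minus leaf, 51% for dissection against uninfected leaf and 53.2% for the added comparison. With an array left out the majority turned for 1 or more arrays in 8 comparisons, the exceptions being infection at the site, amplification and dissection against uninfected leaf.

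With each array left out, calls ranged from 1366 to 1536 at the site, 755 to 1458 for eds16, 525 to 968 for one-round leaf, 659 to 1692 for amplified leaf, 1698 to 2678 for site minus leaf, 91 to 412 for amplified minus one-round (lists 0 to 3), 2430 to 3252 for amplification (lists 5 to 11), 4002 to 9306 for scraped sections, 683 to 4666 for dissection against scrape (lists 4 to 9), 4974 to 6498 for dissection against uninfected leaf and 969 to 1698 for the added comparison. The correlation of site and amplified leaf ranged from -0.402 to -0.343, and that of one-round and amplified leaf from 0.609 to 0.693. The ribosomal median for eds16 ranged from -0.01 to 0.31.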

Other observations

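The comparison in this part was added after the data were seen. Cells of infected eds16 were set against wild-type cells labelled uninfected, a label that ran opposite to whole leaf. FANCM rose by 3.06 ± 0.26 (SE, n = 2 per group, limma adjusted p = 0.000366), AT1G42365 by 2.85 ± 0.48, AT5G01860 by 2.71 ± 0.60 and AT1G69400 by 2.43 ± 0.51. The largest falls were in AT5G03350 (-5.07 ± 0.43, adjusted p = 0.000366), AT3G02560 (-4.66 ± 0.39), AT1G56700 (-4.36 ± 0.14) and GLX2-1 (-4.3 ± 0.30). FANCM, AT5G01860 and AT1G69400 had means below log2 3 in wild type, and AT1G56700 and GLX2-1 in eds16, so their changes are read as lower bounds. AT3G02560 is listed among cytosolic ribosomal proteins, of which 13 of 114 fell (list adjusted p = 1.19e-11; adjusted p = 0.272 with an estimated correlation). Of 10 autophagy genes 5 fell, among them ATG8F (-1.83 ± 0.32) and ATG3 (-1.44 ± 0.20) (list adjusted p = 9.51e-09; adjusted p = 0.0577 with an estimated correlation). Of 8 photosystem genes 3 fell, ATPC1 by -1.44 ± 0.19, PSAE-1 by -1.38 ± 0.22 and PSBW by -0.73 ± 0.14, and PRK of the Calvin cycle fell by 1.37 ± 0.29 as 1 of 3 (list adjusted p = 2.45e-07 and 0.0039; adjusted p = 0.0577 and 0.119 with an estimated correlation). CRT1b (-2.05 ± 0.40) and ATERDJ3B (-1.81 ± 0.40) fell, as 2 of 3 folding genes (list adjusted p = 0.00596; adjusted p = 0.107 with an estimated correlation).

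In the same comparison plastid-encoded lists were higher, with ycf4 (1.67 ± 0.39) and rps16 (1.74 ± 0.40) called, as 1 of 45 and 1 of 20 (list adjusted p = 0.000121 and 6.05e-05; adjusted p = 0.524 for both with an estimated correlation). The thionin gene THI2.1 rose by 1.59 ± 0.34, as 1 of 17 defensin-like and thionin peptides, and AGL57 by 0.96 ± 0.12, as 1 of 40 AGAMOUS-like factors (list adjusted p = 0.0302 and 0.03; adjusted p = 0.272 and 0.584 with an estimated correlation). BIK1 (-2.44 ± 0.53) and STZ (-2.31 ± 0.45), a zinc finger factor listed under touch and wound response, fell. In all 354 probe sets were called higher and 877 lower, and 9 of 24 lists passed, 0 of them with an estimated correlation (4 at an unadjusted p under 0.05; fry 7). The percentage of calls that were higher was 28.8%, 44.1% after quantile normalization (919 calls) and 12.9% with median centring (1321 calls). Without the scraped sections it was 53.2% (2692 calls, 1432 higher and 1260 lower). With only the arrays compared limma called 0 (4506 at an unadjusted p under 0.05), and AT5G01860 and AT1G69400 missed the threshold with some array left out (adjusted p up to 0.118); with only the arrays compared all 8 named genes did (adjusted p up to 0.322). Adjusted over the list alone, 5 of 8 photosystem, 2 of 3 Calvin cycle and 2 of 3 folding genes fell.

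Core histones, beta-glucosidases and serine carboxypeptidase-like proteins passed as lists in none of the 11 comparisons with camera. With fry core histones passed in dissected against uninfected leaf (adjusted p = 0.0192), beta-glucosidases there, at the site and in scraped sections (0.0382, 0.0285 and 0.00734), and carboxypeptidase-like genes there, at the site, in site minus leaf and in the added comparison (0.00254, 0.0431, 0.0113 and 0.0403). In dissected cells labelled uninfected against uninfected amplified leaf, 4 of 9 core histones rose (list median 1.15, adjusted p = 0.23), 4 of 20 beta-glucosidases rose and 4 fell (0.37, adjusted p = 0.517), and 2 of 29 carboxypeptidase-like genes rose and 8 fell (0.11, adjusted p = 0.124). The senescence list had 1 named member, WRKY6, which was called in no comparison and stood at 1.13 in amplified leaf (adjusted p = 0.147).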
